A study of Homo sapiens with 4 samples.

How the data were processed

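RNA-seq libraries from 2 groups of cells were compared, 2 libraries labelled IR-S (IR-sensitive) and 2 labelled IR-R (IR-resistant). The labels give the cells of all 4 libraries as MCF-7, an established line from a breast carcinoma that expresses the estrogen receptor, and as untreated. Total RNA was extracted with a column kit and 1.3 ug entered a SMARTER mRNA-seq library, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b and DESeq2. The program that counted reads and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical paralogs, could not be told apart.

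The raw counts per gene were deposited by the authors in 1 table of 58735 genes for the whole series, with no normalization per the file headers. FPKM values, deposited beside the counts, were the count divided by gene length and by a library total equal to the DESeq2 size factor times the geometric mean of the totals (the ratio of the totals was 1 in each library). The authors also deposited a log2 fold change of IR-R over IR-S. A p-value and an adjusted p-value per gene were deposited with it, for the 23224 genes with at least 2 counts in all. The processing notes name the mouse build mm10, whereas the ID and coordinates of all 58735 rows equalled those of GENCODE 29 on human GRCh38. Coordinates are given on GRCh38, as in the deposited table. In the table, 27 symbols had been turned into dates by spreadsheet software, and these were restored through the gene IDs.

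The libraries held 17383876 counts (IR-S 1), 18168639 (IR-S 2), 18750589 (IR-R 1) and 20176440 (IR-R 2). Replicates were compared by a chi-square test of their counts over genes with at least 20 counts in the pair. The chi-square per degree of freedom was 5.17 for the IR-S pair and 2.57 for the IR-R pair, against 101.7 to 129.8 between groups, so the replicates were distinct libraries. No label says that they came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical. Counting intervals (95%, exact binomial) and the floor of 3 counts summed over the libraries of a group, 0.0834 CPM in IR-S and 0.0781 in IR-R, cover counting error only, since the reads carried no molecular identifiers.

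Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with TMM factors, the filterByExpr filter at its default minimum count of 10, the group as the only term, and Benjamini-Hochberg adjustment over the 14611 genes kept. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of F. CPM values are means over the 2 libraries of a group with their SD (n = 2), scaled by TMM. The 26 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With an estimated correlation, camera takes its degrees of freedom from the replicates, here 2 libraries per group. That setting could call little whatever the data, and its lack of calls decides nothing. Fry, planned beside camera for direction, tests a list alone, without comparing it with the other genes. Neighbouring genes were tested with camera as 290 blocks of 50 tested genes in chromosome order. Data were simulated from the means and depths of these libraries (14292 genes tested), with 49 or 50 genes changed at each fold and no GC trend. There the test recovered 51.0% of genes changed 1.5-fold, 66% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold. It called 9 of 14093 unchanged genes, 5.42% of its calls. With so few changed genes the adjusted threshold is stricter than in the real data, where most genes were called. The recovery rates therefore need not hold here, and false calls that follow GC content were not simulated.

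Before the data were examined, the lists, the tests and the rule for named genes were fixed. The rule took the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. It also took from each list the called member (at least 1 CPM) with the largest rise and the one with the largest fall, and 10 fixed genes (ESR1, PGR, CASP3, CDKN2A, TP53, CDKN1A, CDH1, VIM, CD44 and EGFR). Other genes are named where a list had 5 or fewer members in a direction, in the check of the MCF-7 label and in the closing observations, and these were chosen after their values were seen. Alternatives were DESeq2 size factors, upper-quartile factors or library size for scaling, no filter or at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1), protein-coding genes alone, the replicate block, and each library left out. With 1 library left in a group, that library was assumed to vary like the pair of the other group. Genes were filtered anew in these fits, so a list or family could have other members tested. A correction for transcript GC content (a loess trend with span 0.3 removed per library as an offset, with 8 genes that had no value set to the median) was added after the data were seen.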

Results

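Gene expression was measured in 4 libraries, 2 from cells labelled IR-sensitive MCF-7 (IR-S) and 2 from cells labelled IR-resistant MCF-7 (IR-R), a line the series title calls radioresistant, to find the genes that differ between the lines. The libraries held 17383876 to 20176440 counts. Mitochondrially encoded transcripts took 3.17% and 3.19% of the counts in IR-S and 2.40% and 2.22% in IR-R.

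The MCF-7 label was checked first. ESR1, the estrogen receptor that MCF-7 cells are known to express (ENSG00000091831, chromosome 6, 151656691 to 152129619), had 1 count in IR-S 1 and 0 in the other 3 libraries. PGR, the progesterone receptor (ENSG00000082175, chromosome 11, 101029624 to 101130524), had 0 counts in all 4, which allows up to 0.0834 CPM in IR-S and 0.0781 in IR-R. The luminal transcription factor GATA3 had 4 to 11 counts, KRT19 1 to 6, and the E-cadherin gene CDH1 5 to 15, with no detectable difference of CDH1 between groups (log2 fold change 0.30 ± 0.60 SE, edgeR adjusted p = 0.683). CDKN2A, a cell cycle inhibitor known to be deleted in MCF-7 (ENSG00000147889, chromosome 9, 21967753 to 21995301), had 7734 and 7821 counts in IR-S and 12609 and 14715 in IR-R. It was 1.64-fold higher in the IR-R libraries (log2 0.72 ± 0.05 SE, adjusted p = 1.79e-10). CASP3, the executioner caspase that MCF-7 is known to lack in functional form, had 76 and 96 counts in IR-S and 37 and 37 in IR-R. The luminal keratins KRT8 and KRT18 were abundant, with at least 15928 counts in each library. The near absence of ESR1, PGR, GATA3, KRT19 and CDH1 and the abundant CDKN2A contradict the MCF-7 label in all 4 libraries. The counts of CASP3, KRT8 and KRT18 do not speak against it. IR-S and IR-R therefore stand in the text only for the labels of the libraries, and each direction is one between libraries so labelled.

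**Figure D1:**
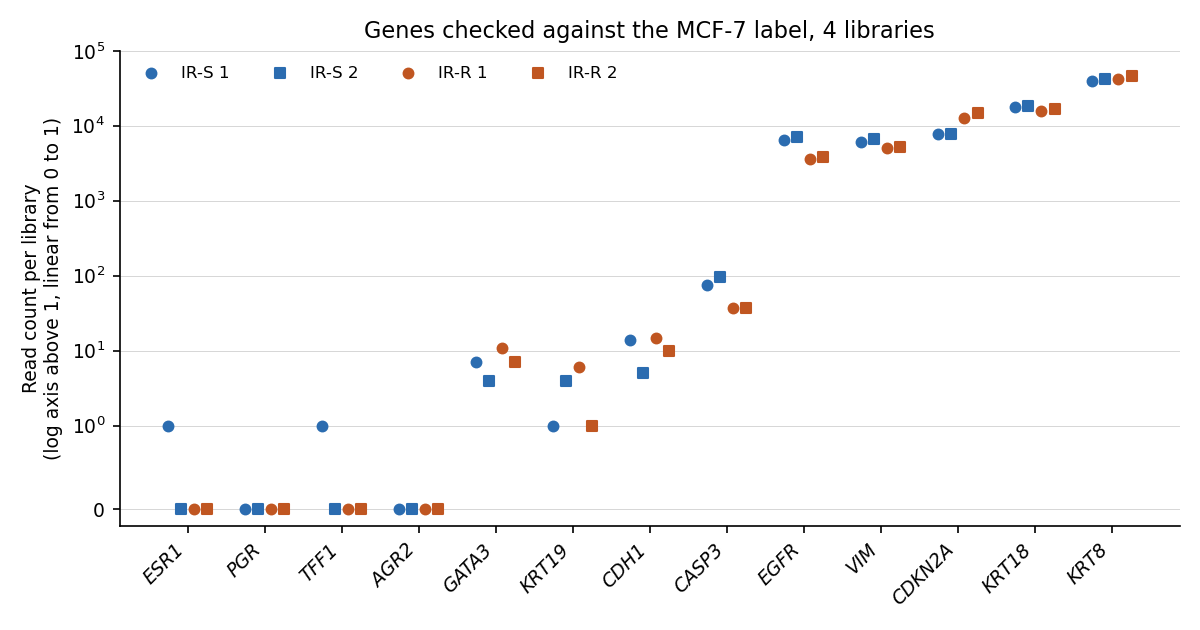
Read counts of 13 genes in each of the 4 libraries (points, 1 per library), on an axis that is logarithmic above 1 and linear from 0 to 1. ESR1 and PGR lie at 0 or 1 count in all libraries, whereas CDKN2A lies between 7734 and 14715.

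Between the libraries labelled IR-R and IR-S, 4466 genes were higher and 4679 lower in IR-R, 62.59% of the 14611 tested. At least 2-fold differences were called for 1866 higher and 1438 lower genes. Among called protein-coding genes with a mean of at least 10 CPM in the higher group, FN1, which encodes the matrix protein fibronectin, had the largest rise, from 10.4 ± 0.65 to 670.2 ± 9.2 CPM (SD, n = 2), a 64.1-fold difference (log2 6.0 ± 0.07 SE, adjusted p = 2.27e-21). The melanoma antigen gene MAGEC1 was read only in IR-S, with 186 and 183 counts against 0 and 0, at least 131.4-fold lower in IR-R against the floor of 3 counts over the group.

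Another 5 genes had large rises in the IR-R libraries. The orphan receptor gene GPR173 rose 39.9-fold (log2 5.32 ± 0.32 SE) and EDN2, which encodes the vasoconstrictor peptide endothelin 2, rose 34.0-fold to 83.5 ± 3.2 CPM. ABCG1, a cholesterol exporter, rose 30.7-fold (log2 4.94 ± 0.33 SE). Its log2 change was 6.05 without IR-S 1 and 4.28 without IR-S 2. The apoptosis inhibitor gene BIRC7 rose 28.2-fold to 57.4 ± 1.5 CPM, with a log2 change of 4.82 that the correction for GC content took to 4.23. BMF, which encodes a BH3-only promoter of apoptosis, rose 25.9-fold to 14.5 ± 0.44 CPM. The edgeR adjusted p of these 5 genes lay between 6.39e-16 and 3.06e-10.

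RBBP8NL fell from 488 and 216 counts (27.8 and 11.7 CPM) to 1 and 0, a ratio of CPM of 732.4 with a 95% interval of 134.5 to 29730 that covers counting error only. Its fitted log2 change of −9.23 was −8.50 without IR-S 1, −11.52 without IR-R 1 and −8.34 without IR-R 2. FABP5, a fatty acid carrier, fell from 354 and 380 counts to 2 and 0, a ratio of 377.8 with an interval of 108.1 to 3242. The fitted log2 change of FABP5 was −8.44, and −11.57 without IR-R 1 and −7.48 without IR-R 2. The cancer-testis antigen gene CTAG2 fell 119.7-fold (log2 −6.90 ± 0.19 SE), although some of its reads could be shared with its paralog CTAG1B. SPINK6, a protease inhibitor gene, fell 25.03-fold from 43.9 ± 1.5 CPM, and the sorting receptor gene SORL1 fell 21.7-fold from 11.4 ± 0.52 CPM. The log2 change of SORL1 was −4.44, and −5.37 without IR-R 2. The adjusted p of these 5 genes lay between 1.46e-15 and 4.35e-10.

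**Figure D2:**
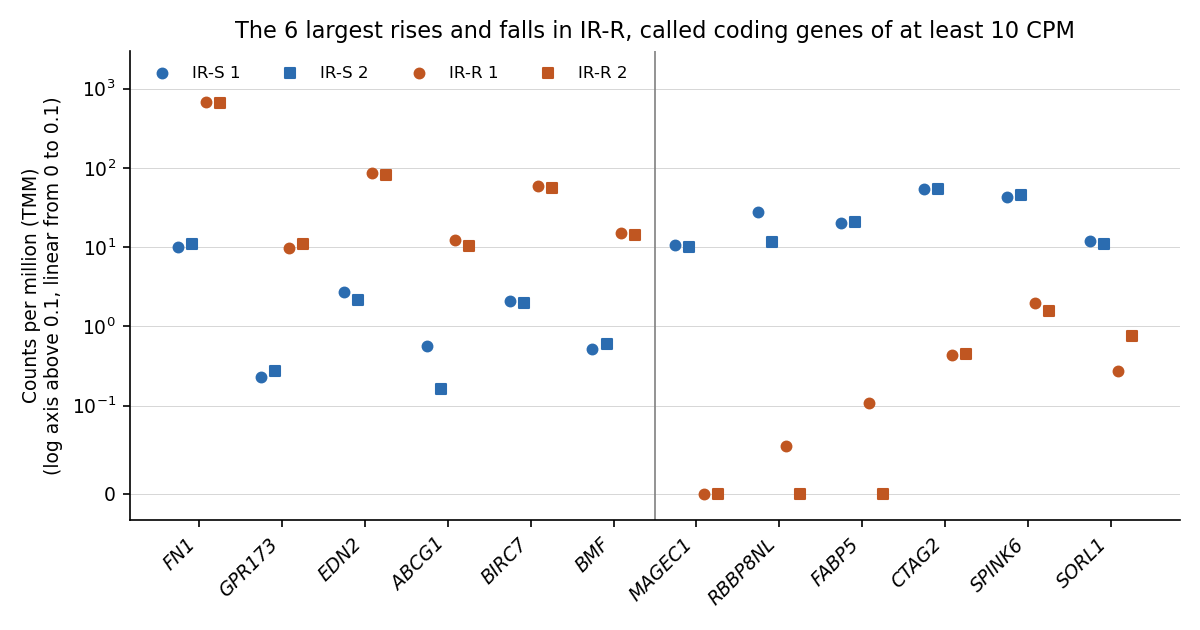
CPM of the 6 genes with the largest rises (left of the line) and the 6 with the largest falls (right) in IR-R, among called protein-coding genes with a mean of at least 10 CPM in the higher group, 1 point per library, on an axis that is logarithmic above 0.1 and linear from 0 to 0.1. FN1 lies near 670 CPM in both IR-R libraries and near 10 in both IR-S libraries, and MAGEC1 lies at 0 in both IR-R libraries.

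The rises lay on GRCh38 at chromosome 2, 215360440 to 215436172 (FN1, ENSG00000115414), chromosome X, 53049091 to 53080615 (GPR173, ENSG00000184194), chromosome 1, 41478775 to 41484673 (EDN2, ENSG00000127129), chromosome 21, 42199689 to 42297244 (ABCG1, ENSG00000160179), chromosome 20, 63235883 to 63240507 (BIRC7, ENSG00000101197) and chromosome 15, 40087890 to 40108892 (BMF, ENSG00000104081). The falls lay at chromosome X, 141903894 to 141909388 (MAGEC1, ENSG00000155495), chromosome 20, 62410237 to 62427533 (RBBP8NL, ENSG00000130701), chromosome 8, 81280363 to 81284777 (FABP5, ENSG00000164687), chromosome X, 154651972 to 154653579 (CTAG2, ENSG00000126890), chromosome 5, 148202794 to 148215137 (SPINK6, ENSG00000178172) and chromosome 11, 121452203 to 121633693 (SORL1, ENSG00000137642).

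Fold changes followed the GC content of transcripts. Over 14603 genes, which are not independent replicates, the Spearman correlation of log2 fold change with GC content was 0.437, and it lay between 0.366 and 0.477 in the 4 pairs of an IR-R with an IR-S library. In the decile of genes with the lowest GC content (median 37.3%) 6.84% were higher and 40.4% lower, and in the decile with the highest (64.5%) 62.2% were higher and 11% lower. The ratio of IR-S 1 to IR-S 2 had a correlation of 0.407 with GC content, and that of IR-R 1 to IR-R 2 one of −0.0549. With the correction for GC content, 4004 genes were higher and 4616 lower. Of the 9145 calls, 6571 kept their call and direction and 334 were called in the opposite direction. Without IR-S 2, 4312 genes were higher and 4442 lower.

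**Figure D3:**
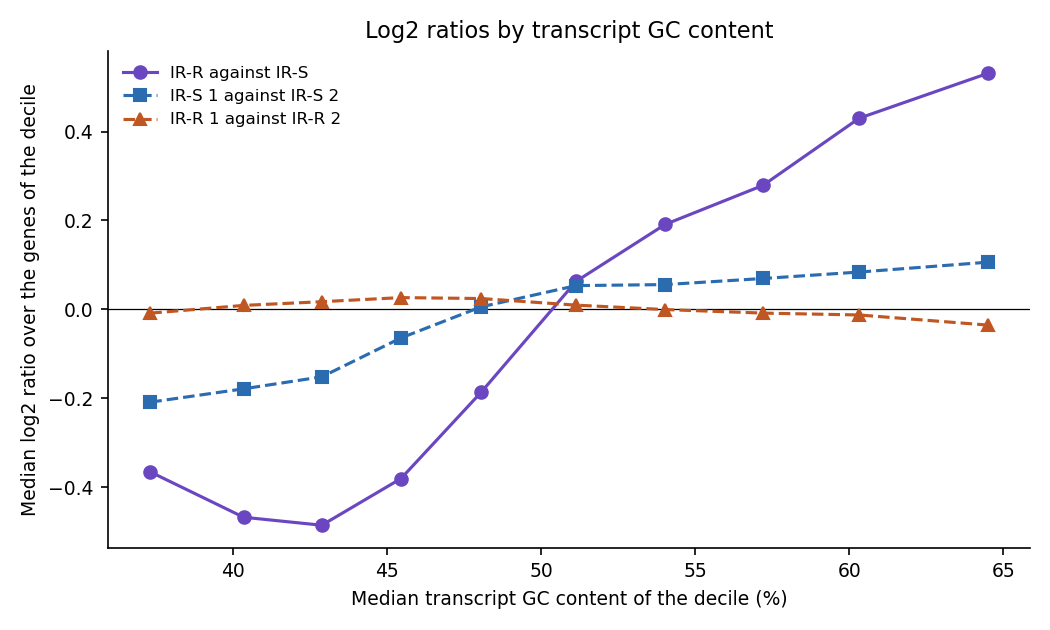
Median log2 ratio over the genes in each decile of transcript GC content (vertical axis) against the median GC content of that decile in percent (horizontal axis), for IR-R against IR-S (solid) and for the replicates within each group (dashed). The IR-R against IR-S median goes from −0.366 in the lowest decile to 0.531 in the highest, and the IR-S replicates follow a smaller slope from −0.209 to 0.106.

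Genes of hypoxia and glycolysis were higher in the IR-R libraries. Of 30 members 22 rose, and the 3 that fell were ADM (a vasodilator peptide), PDK1 (a brake on pyruvate oxidation) and LDHA (lactate dehydrogenase A). CA9, the hypoxia-induced carbonic anhydrase, rose from 4.94 ± 2.77 to 56.6 ± 1.5 CPM (11.5-fold, log2 3.53 ± 0.19 SE), with a log2 change of 4.23 without IR-S 1. ADM fell 1.53-fold from 115.1 ± 7.0 CPM. Camera gave an adjusted p of 3.5e-10, which was 7.59e-11 after the correction for GC content. This was one of 10 lists called, and with an estimated correlation the adjusted p of the 10 lay between 0.401 and 0.551, so that no list was called. That setting cannot decide, since a list with a negative estimated correlation, the mesenchymal genes (−0.0153), lost its call too. Estimated correlations were 0.31 for hypoxia and glycolysis, 0.616 for mitochondrially encoded genes and 0.143 for luminal identity, against the preset of 0.01. The camera adjusted p of these lists at the preset may therefore be too small. Of the hypoxia and glycolysis genes, 25 passed when adjusted over the list alone.

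Mesenchymal genes were also higher as a list. Of 24 tested members 13 rose, led by FN1, and 7 fell, led by THBS1 (thrombospondin 1), which was 6.94-fold lower (log2 −2.80 ± 0.08 SE). The intermediate filament gene VIM fell 1.32-fold from 353.3 ± 6.1 to 266.8 ± 3.3 CPM and the hyaluronan receptor gene CD44 fell 1.98-fold from 569.8 ± 3.6 to 288.3 ± 5.7 CPM. The camera adjusted p was 7.54e-06, 3.69e-07 after the correction for GC content and 0.401 with an estimated correlation. There were 20 members that passed when adjusted over the list alone.

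Targets of p53 were higher, and TP53 itself rose 1.76-fold to 164.0 ± 1.8 CPM (log2 0.82 ± 0.06 SE, adjusted p = 6.15e-10). Of 27 tested targets 14 rose, among them GDF15, a stress cytokine gene (16.1-fold, log2 4.01 ± 0.11 SE), and the cell cycle inhibitor gene CDKN1A, from 59.1 ± 7.2 to 365.9 ± 16.1 CPM (6.20-fold, log2 2.63 ± 0.07 SE). The 5 that fell, against the direction of the list, were PLK2 (6.50-fold), FBXW7, PPM1D, MDM2 and TRIAP1. PPM1D and MDM2 encode known negative regulators of p53 but stand in the list as its targets. The activity of p53 itself was not measured. Without IR-R 1, and after the correction for GC content, 3 targets fell. The camera adjusted p was 9.07e-05, 1.69e-05 after the correction for GC content and 0.401 with an estimated correlation, and 19 members passed when adjusted over the list alone.

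DNA replication and G1/S genes were lower in the IR-R libraries. Of 36 members 24 fell, among them GINS3, a subunit of the replicative helicase complex (2.35-fold, log2 −1.23 ± 0.15 SE). The 3 that rose were the licensing factor gene CDT1 and the transcription factor genes E2F1 and E2F2. The rise of CDT1 (log2 0.47 ± 0.05 SE) became −0.11 after the correction for GC content, with an adjusted p of 0.061. For the list the camera adjusted p was 0.00021, and 0.000335 after the correction, with 0 members higher. It was 0.401 with an estimated correlation. Of the members, 27 passed when adjusted over the list alone.

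All 13 messenger RNAs of the mitochondrial genome fell, and the ribosomal RNAs MT-RNR1 (log2 0.16, adjusted p = 0.0512) and MT-RNR2 (log2 −0.13, adjusted p = 0.0712) did not pass. MT-CYB fell 1.83-fold from 1118 ± 4.9 to 609.7 ± 43.2 CPM and MT-CO3 fell 1.61-fold (log2 −0.68 ± 0.04 SE). Both encode respiratory chain subunits. The camera adjusted p was 3.7e-05, 0.403 after the correction for GC content and 0.551 with an estimated correlation. After the correction 6 members fell and 2 rose, and the median went from −0.447 to −0.0622, and without IR-S 2 or IR-R 2 there was 1 that rose. All 15 members passed when adjusted over the list alone.

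Interferon-stimulated genes, genes of the unfolded protein response and NRF2 antioxidant genes were higher as lists with smaller medians, though none was called with an estimated correlation. Of 29 tested interferon-stimulated genes 16 rose, among them the exonuclease gene ISG20 (4.37-fold, log2 2.13 ± 0.21 SE), and IFIT5 (2.11-fold), PARP9 and STAT1 fell (camera adjusted p = 0.00719, and 0.401 with an estimated correlation). After the correction for GC content 14 rose and 5 fell. Of 24 unfolded protein response genes 13 rose, among them CHAC1, a glutathione-degrading enzyme gene (5.61-fold, log2 2.49 ± 0.23 SE, and 3.10 without IR-S 1). The 5 that fell were SEL1L, DNAJC3, EDEM1, HSP90B1 and HSPA5, which encode chaperones and degradation factors of the endoplasmic reticulum (camera adjusted p = 0.0238, and 0.546 with an estimated correlation). Without IR-S 2, 3 genes of the list fell, and 2 after the correction for GC content. Of 27 tested NRF2 genes 13 rose, among them AKR1B10, from 2 and 13 counts to 34 and 37 (log2 2.14 ± 0.54 SE, 1.37 without IR-S 1 and 3.93 without IR-S 2). Another 8 NRF2 genes fell, among them the glutathione synthesis gene GCLC (2.29-fold). Without IR-R 2, 5 fell. The adjusted p of the NRF2 list was 0.0408, 0.551 with an estimated correlation, 0.0715 without IR-S 1 and 0.0574 without IR-S 2, and it was 0.0569 with scaling by library size, 0.107 without a filter and 0.0688 with the CPM filter of 5. After the correction for GC content the 3 lists had adjusted p of 0.0144, 0.0103 and 0.00153, in this order. Adjusted over the list alone, 19, 18 and 21 members passed.

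Of the 18 luminal identity genes 11 were tested and 7, ESR1, GATA3, KRT19, TFF3, AGR2, AGR3 and MLPH, did not pass the filter on low counts. ERBB3, a HER family receptor gene, rose from 2.49 ± 0.68 to 22.045 ± 1.54 CPM (8.88-fold, log2 3.15 ± 0.20 SE) and was among 6 that rose, and FOXA1 (2.44-fold lower, log2 −1.29 ± 0.18 SE) and KRT18 fell. The camera adjusted p was 0.0278, but 0.186 without IR-S 2, 0.15 after the correction for GC content, 0.105 without a filter, 0.0594 with the CPM filter of 5 and 0.551 with an estimated correlation. After the correction 6 rose and 5 fell, and the median went from 0.271 to 0.256. When adjusted over the list alone, 8 passed. Of 21 fibroblast and endothelial markers 8 were tested and 4 rose, PDGFRB (9.12-fold, log2 3.19 ± 0.14 SE), COL1A1 (2.47-fold), COL5A1 and COL6A1. Other stromal genes of that list, COL1A2, FAP, PDGFRA and POSTN, had 0 counts in all 4 libraries. The camera adjusted p was 0.00421, 0.0565 after the correction for GC content (median 0.707 before and 0.534 after) and 0.401 with an estimated correlation, with 4 passing when adjusted over the list alone.

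The lists of DNA repair were not called by camera. By fry, damage signalling was lower (adjusted p = 0.0209), while homologous recombination (0.115) and end joining (0.0973) did not pass. Of 35 tested genes of homologous recombination and Fanconi anaemia 12 fell and 4 rose (camera adjusted p = 0.484), and the 4 were XRCC3, RAD54L, FANCF and FANCG. XRCC3, a RAD51 paralog, had a log2 change of 0.73 ± 0.10 SE, and 0.19 with an adjusted p of 0.0887 after the correction for GC content. GEN1, a junction resolvase gene, was lower (log2 −1.09 ± 0.45 SE, adjusted p = 0.0435), but lost its call without IR-S 2 (log2 −0.76, adjusted p = 0.334), IR-R 1 (−0.92, 0.217) or IR-R 2 (−1.27, 0.103) and after the correction for GC content (−0.67, 0.2). Without IR-R 2, 7 genes of the list fell and 2 rose, and after the correction 7 fell and 3 rose. Of 18 end joining genes 7 fell, led by the Ku subunit gene XRCC5 (2.24-fold, log2 −1.16 ± 0.10 SE), and 5 rose, PAXX, MAD2L2, POLL, PNKP and SHLD1 (camera adjusted p = 0.484). SHLD1 (log2 0.71 ± 0.27 SE, adjusted p = 0.0271) lost its call without IR-S 2 (log2 0.51, adjusted p = 0.138) and without IR-R 1 (0.57, 0.196). Without IR-R 1, 3 genes of the list rose, and after the correction for GC content 2 rose and 8 fell. Of 26 damage signalling genes 12 fell, led by the checkpoint clamp gene RAD1 (2.88-fold, log2 −1.52 ± 0.07 SE), and 5 rose, TP53, CHEK2, RAD9A, MDC1 and PKMYT1 (camera adjusted p = 0.181). Without IR-S 2, IR-R 1 or IR-R 2, 3 of that list rose. In the 3 lists 13, 12 and 17 members passed when adjusted over the list alone.

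Of 36 G2/M and mitosis genes 16 fell and 6 rose, and 2 rose without IR-R 1 or IR-R 2 (camera adjusted p = 0.181). AURKB, a mitotic kinase gene, rose 1.54-fold, and the kinetochore motor gene CENPE (log2 −1.45 ± 0.50 SE, adjusted p = 0.0165) lost its call without IR-S 2 (−1.21, adjusted p = 0.179), IR-R 1 (−1.58, 0.0718) or IR-R 2 (−1.32, 0.126) and after the correction for GC content (−1.13, 0.0537). After the correction 10 genes of the list rose and 13 fell (median −0.225 before and −0.0444 after, camera adjusted p = 0.83). Of 30 apoptosis regulators 10 rose and 8 fell (camera adjusted p = 0.619), and 11 rose and 5 fell after the correction, with BMF the largest rise and CASP3 the largest fall (2.47-fold, log2 −1.31 ± 0.26 SE, adjusted p = 0.000271). Of 26 HER and growth factor genes 12 rose and 10 fell (camera adjusted p = 0.913). EGFR fell 1.93-fold from 372.1 ± 9.9 to 192.7 ± 2.2 CPM (log2 −0.95 ± 0.05 SE) and the ligand gene AREG fell 4.33-fold (log2 −2.12 ± 0.21 SE). Adjusted over the list alone, 22, 18 and 22 members of these lists passed.

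Of 21 tested estrogen response genes 8 rose and 5 fell (camera adjusted p = 0.484), with the early response gene EGR3 the largest rise, from 7 and 4 counts to 142 and 160 (25.1-fold, log2 4.65 ± 0.34 SE). The 5 that fell were AREG, PRSS23, CCND1, SLC39A6 and FKBP4. Of 15 basal epithelial genes 6 rose, led by the keratin gene KRT16 (6.12-fold), and 8 fell, led by the integrin gene ITGA6 (2.72-fold; camera adjusted p = 0.587). Of 19 junction genes 6 rose, led by TJP3 (19.5-fold, log2 4.28 ± 0.22 SE), and 8 fell, led by EPCAM (6.48-fold, log2 −2.70 ± 0.30 SE; camera adjusted p = 0.504). Of 17 stem cell markers 9 rose and 5 fell (camera adjusted p = 0.0854). SOX2 rose from 0 and 1 counts to 23 and 18, a ratio of 39.6 with a 95% counting interval of 6.52 to 1553. Its fitted log2 change was 4.96, and 4.14 without IR-S 1 and 7.33 without IR-S 2. The 5 that fell were ITGA6, BMI1, CD44, JAG1 and ALDH1A3. Adjusted over the list alone, 13, 14, 14 and 14 members of these 4 lists passed.

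Of 23 tested NF-kB targets and cytokines 11 rose, led by IGFBP3 (6.05-fold, from 73.2 ± 12.1 to 442.4 ± 6.3 CPM), and 5 fell, TNFRSF11B, PTGS2, CXCL2, IGFBP7 and NFKB1 (camera adjusted p = 0.0607). TNFRSF11B had 19 and 33 counts in IR-S against 2 and 5 (log2 −2.94 ± 0.60 SE, and −3.66 without IR-R 2). The list passed with the CPM filter of 5 (camera adjusted p = 0.0373) and with the replicate block (0.0443). It also passed without IR-S 1, IR-R 1 or IR-R 2, where its median of 0.368 became 0.0147, 0.106 and 0.396. It did not pass without IR-S 2 (0.186), after the correction for GC content (0.177) or with an estimated correlation (0.502), and 8 members fell without IR-S 2. Of 28 immediate-early and heat shock genes 17 rose, led by EGR3, and 8 fell, led by the chaperone gene HSPA8, from 3538 ± 86.0 to 802.6 ± 15.7 CPM (4.41-fold, log2 −2.14 ± 0.04 SE; camera adjusted p = 0.797, test up). After the correction for GC content 11 rose and 10 fell, with the test down (adjusted p = 0.296). Of 25 cholesterol synthesis genes 12 rose, led by TM7SF2 (log2 0.98, and 0.43 with adjusted p = 0.0524 after the correction for GC content), and 7 fell, led by HMGCS1 (2.02-fold; camera adjusted p = 0.348). After the correction 7 rose and 6 fell. Of 19 antigen presentation genes 6 rose, led by the immunoproteasome gene PSMB9 (2.48-fold), and 7 fell, led by the chaperone gene CANX (2.17-fold; camera adjusted p = 0.783). Adjusted over the list alone, 17, 25, 19 and 13 members of these 4 lists passed.

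Of 19 tested replication-dependent histone genes 4 rose, HIST1H2BJ (log2 0.83 ± 0.17 SE), HIST1H2BD, HIST1H2AE and HIST1H2AC, and 2 fell, HIST1H4H (log2 −1.33 ± 0.27 SE) and HIST1H2BH (camera adjusted p = 0.913, 6 passing when adjusted over the list alone). Without IR-R 2, 1 fell. Reads of these near-identical histone copies could be shared between them. Of 20 blood cell markers 5 were tested, CSF1R and CD19 rose (log2 1.77 ± 0.43 and 1.28 ± 0.41 SE, at most 2.37 CPM) and 0 fell, with 2 passing when adjusted over the list alone (camera adjusted p = 0.826). CD19 lost its call without IR-S 2 (log2 0.98, adjusted p = 0.0501), without IR-R 2 (0.68, 0.345) and after the correction for GC content (0.87, 0.0734), when 1 marker rose. The log2 change of CSF1R was 2.37 without IR-S 2, and 1 blood marker fell without IR-S 2, IR-R 1 or IR-R 2. The leukocyte genes PTPRC and TYROBP had 0 counts in all 4 libraries.

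In several lists the median log2 change, the mean and the direction of camera differed in sign. The median was negative and the mean positive for estrogen response (−0.0685 and 0.162, test up), junctions (−0.0444 and 0.161, test up), apoptosis regulators (−0.0104 and 0.229, test up), blood cell markers (−0.0966 and 0.401, test up) and basal epithelium (−0.287 and 0.0655, test down). Both were positive for HER signalling (0.00834 and 0.11) with the test down, and for histones the median was 0.176 and the mean −0.0112 with the test up. None of these lists was called by camera. By fry, estrogen response (adjusted p = 0.0301) and junctions (0.0178) passed upward and basal epithelium (0.0166) downward. Apoptosis regulators (0.0508), blood cell markers (0.122), histones (0.332) and HER signalling (0.867, with the direction up) did not pass. Fry was not run after the correction for GC content, for these lists or for those of DNA repair. With ESR1 at 1 or 0 counts in each library, the estrogen response list does not show a change of estrogen receptor signalling. DESeq2 did not call GEN1, SHLD1, CENPE or CD19, with log2 changes of −1.08, 0.73, −1.44 and 1.30 and adjusted p of 0.248, 0.159, 0.157 and 0.0811. GEN1 also lost its call with limma-voom (log2 −1.05, adjusted p = 0.0539). With limma on log2(FPKM + 1) and log2(FPKM + 0.1), GEN1 had adjusted p of 0.198 and 0.0999.

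**Figure D4:**
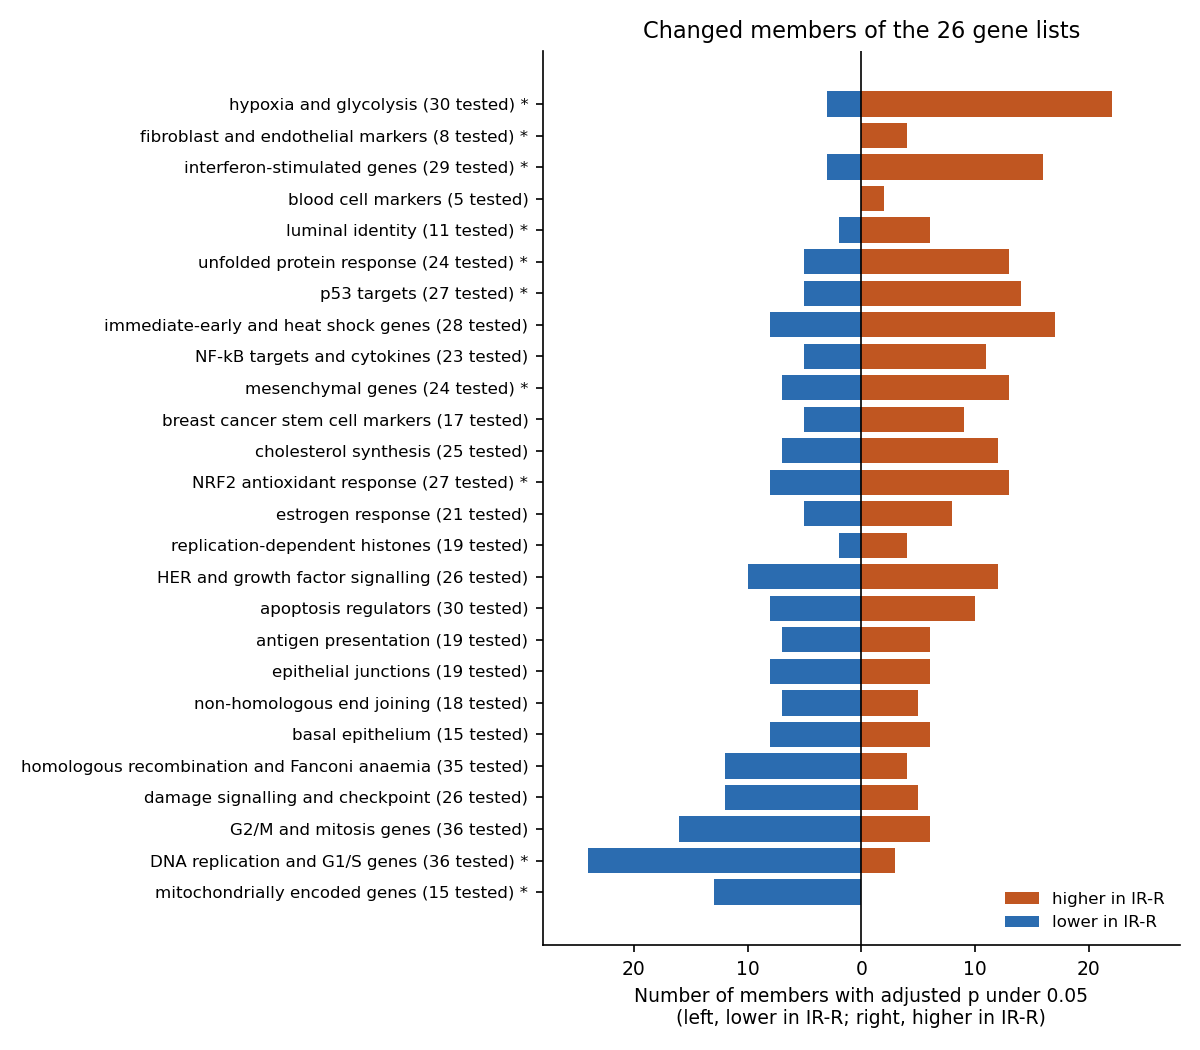
Number of members of each of the 26 lists called higher (right) and lower (left) in IR-R by edgeR at an adjusted p under 0.05, with the number tested in parentheses and an asterisk on lists with a camera adjusted p under 0.05 at the preset correlation. Hypoxia and glycolysis has 22 members higher and 3 lower, and DNA replication and G1/S genes 3 higher and 24 lower.

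In the authors' deposited table, 7470 genes had an adjusted p under 0.05, of which 3845 were higher and 3625 lower in IR-R. At least 2-fold differences were called for 1647 higher and 1153 lower genes in the authors' deposited table. Of its 7470 genes, 7392 were called here in the same direction and 0 in the opposite direction. Another 76 of them were not tested by edgeR because of the filter on low counts. DESeq2 run on the deposited counts called 7523 genes, among them all 7470 of the authors' deposited table. Both analyses used the same libraries, so that the overlap is no independent check.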

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

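The correction for GC content and its combination with the replicate block were chosen after the data were seen, and the other alternatives before. The counts of genes higher and lower in IR-R stayed within 1.5 times their values under every alternative run. Leaving out each library gave 3772 to 4582 genes higher and 3883 to 4823 lower. The replicate block gave 4460 higher and 4688 lower. The deviations of same-numbered libraries had a correlation of 0.0267 over 14611 genes, which shows no pairing by number. It cannot exclude one, since the IR-S replicates differed along GC content (Spearman correlation 0.407, against −0.0549 in IR-R), which could hide a shared effect. At least 2-fold differences numbered 1116 higher and 856 lower with the filter of 5 CPM, which tests 10075 genes, and 834 and 409 on log2(FPKM + 1), a scale that understates changes of low genes. The 10 lists called became 0 with an estimated correlation, 7 after the correction for GC content, and 8 to 11 when a library was left out. Over the lists, 299 values kept direction and call, 23 lost the call and 5 gained it. All 5 gains, the replicate block (adjusted p = 0.0443) included, were of the NF-kB list. Of values for named genes 1046 were the same and 27 lost the call. Blocks of neighbouring genes called higher (41) numbered 27 in blocks of 100 genes, 0 with an estimated correlation and 5 after the correction for GC content, and blocks called lower (19) numbered 11, 0 and 9. Larger blocks are fewer, the estimated correlation had too few degrees of freedom to decide, and the cause of the other changes was not tested.

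The direction of the test changed in 5 lists that were not called, and the sign of the fold change in CDT1 and CDH1, and the cause was not tested. After the correction for GC content, without and with the replicate block, the medians were −0.0239 and −0.0227 for homologous recombination and −0.00571 and −0.00123 for immediate-early genes, and CDT1 had −0.1064 and −0.1069. Without a filter, medians were 0.368 for HER signalling and −0.464 for blood cell markers. With a library left out, medians ranged from −0.12 to 0.119 for histones and from −0.416 to 0.385 for blood cell markers, and CDH1 ranged from −0.2953 to 1.238. At 17383876 to 20176440 counts per library, depth limits statements on genes near the floor, such as ESR1, PGR and CDH1.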

Other observations

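Several gene families differed between the libraries labelled IR-R and IR-S, of 10 examined, and some of their members (collagens, claudins, integrins and proteasome subunits) also stand in the lists. Cancer-testis antigens, the chaperonin and the splicing factors were chosen after their members were seen, so that their tests only describe these libraries. Of 15 tested cancer-testis antigen genes, normally limited to the germ line, 9 fell and 2 rose (GAGE2A, log2 1.60, and PAGE1, 1.75). MAGEA12 (log2 −2.93), MAGEA11 (−3.48) and XAGE2 (−3.79) fell with MAGEC1 and CTAG2, whereas MAGEA1 stood at 154.7 and 145.9 CPM (adjusted p = 0.185). The family median was −1.28. In fits that filtered genes anew, and so could test other members, the family median was −0.545 without IR-S 1 and −0.562 without IR-S 2. It was −0.949 without IR-R 1 and −1.18 without IR-R 2. Reads of this family could be split between near-identical copies. All 10 families had adjusted p of 0.205 to 0.791 with an estimated correlation. Of 8 subunits of the CCT chaperonin, which folds actin and tubulin, 7 fell, led by CCT2 (log2 −2.03), and of 11 SRSF splicing factor genes 10 fell, led by SRSF1 (−2.03), while SRSF9 rose (0.38). Their camera adjusted p were 6.54e-08 and 3.55e-10, and both were 0.205 with an estimated correlation and 1.09e-05 after the correction for GC content.

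Among families chosen before their members were seen, 5 of 8 claudin genes of tight junctions rose, CLDN4, CLDN7, CLDN23, CLDN9 and CLDN3, with CLDN7 at 27.3 and 131.0 CPM (log2 2.26), and CLDN1 fell (adjusted p = 0.00502, 0.00643 after the correction for GC content and 0.207 with an estimated correlation). Proteasome subunits were lower, with 19 of 37 falling and 8 rising (adjusted p = 0.00551, 0.048 after the correction and 0.335 with an estimated correlation). Their median of −0.322 was −0.212 without IR-S 2 and −0.186 without IR-R 1. Collagen chains were higher, with 13 of 23 rising and 5 falling (adjusted p = 0.00551, median 0.645), but not after the correction (0.477, median 0.175) or with an estimated correlation (0.205). Directions of these families held under all 3 other scalings. Ribosomal proteins (0.0921), aminoacyl-tRNA synthetases (0.659), integrins (0.456) and ZNF genes (0.272) were not called. By a rule set after the data were seen, at least 50 counts in each library of a group and at most 3 in all in the other, 7 genes were present in IR-S alone and 5 in IR-R alone. Those of IR-S were FABP5, RBBP8NL, MAGEC1, TCN2 (at least 102.3-fold lower in IR-R), ACOT4 (at least 89.7-fold), RSPO3 and PLEKHG1 (at least 45.7-fold). Those of IR-R were C16orf54, GNG7, DEPP1, VPS37D and OR2I1P.

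In what follows, the tests of the MCF-7 markers and of the chromosomal runs were chosen after the results were seen. Markers of MCF-7 were near 0 counts in all 4 libraries. Too little depth could hide only levels near the floor, since 0 counts of PGR allow up to 0.0834 CPM in IR-S and 0.0781 in IR-R. KRT8 and KRT18, with at least 15928 counts in each library, are too abundant to test this. A loss in the resistant line is argued against by the IR-S libraries, in which ESR1, GATA3 and KRT19 together had 17 counts. CDKN2A is known to be deleted in MCF-7, and its lowest count was 7734. With the near absence of ESR1 and PGR, this argues against the MCF-7 label. Cells other than MCF-7 in all 4 libraries are left as the candidate source. Which cells these were was not examined, and whether IR-S and IR-R share an origin stays open.

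Log2 fold changes rose with transcript GC content. Transcript length in place of GC content is argued against by a partial Spearman correlation of 0.415 over genes with GC content given length. The IR-S replicates, which share a label, differed along GC content (0.407, and 0.56 above 10 CPM). Libraries of that group thus varied along GC content, by GC bias or otherwise. The IR-R pair (−0.0549, and −0.173 above 10 CPM, the sign set by numbering alone) did not reach the size of 0.1 set beforehand over all genes. How far GC bias from library to library contributes to the trend between groups therefore stays open. A bias shared by the libraries of a group cannot be told apart from a difference between the cells, because each pair of libraries across groups showed the trend (at least 0.366) and the labels give no batch that crosses the groups. A biological difference between the lines stays open too, as untested.

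Neighbouring genes shifted together, and 60 of 290 blocks were called (0 with an estimated correlation), of which 12 kept their call and direction after the correction for GC content. Chance placement is argued against, because the GC-corrected medians of adjacent blocks had a correlation of 0.322, larger than in any of 10000 shuffles (highest 0.241, one-sided permutation p = 1e-04, the smallest possible). Runs were 3 or more adjacent blocks called in 1 direction. The 5 runs were picked by those calls and their camera p adjusted over these 5 alone, so these p only describe the libraries. The correction used transcript GC content, and that of the regions was not measured. Transcript GC content may account for the run on chromosome 11 (62806897 to 68050895, median 0.346 and −0.0442 after correction, adjusted p = 0.972). It may also account for the runs on chromosome 19 (60951 to 18928633, 0.403 and 0.0283, and 44025342 to 49878351, 0.519 and 0.084, both 0.288). However, 1 of 9 blocks of the longer run (17292609 to 18928633, median 0.691 and 0.383) kept its call (0.0262). The correction did not remove all of the lower expression on chromosome 5 (196871 to 56003649, 90 of 150 genes lower and 74 after correction, median −0.592 and −0.482, adjusted p = 1.85e-06). There, 1 of 3 blocks lost its call (38474963 to 56003649, −0.655 and −0.335, 0.0507). Lower expression also remained on chromosome 14 (60709528 to 102342702, 120 of 200 lower and 118 after correction, −0.649 and −0.573, adjusted p = 4.67e-07). A candidate explanation is a difference in copy number of these regions between the lines, a hypothesis that no DNA data here could test.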
